A study of Homo sapiens with 8 samples.

How the data were processed

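Polyadenylated RNA of RD18 cells was sequenced in 8 libraries, 4 transfected with lipofectamine alone and 4 with miR-449a and miR-340, each taken at 60 h. Libraries were made with a stranded mRNA kit and sequenced on a HiSeq4000 instrument, per the labels. The deposited values are whole-number read counts per gene symbol, 1 column per library. The submitters' processing notes name TopHat2 2.0.13, SAMtools 0.1.19.24, HTSeq 0.5.3p3, DESeq2 and the build GRCh38, without saying what each was used for. The gene annotation and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes may share reads. Each column was matched to a sample through the library code in the sample's description, and groups came from the labels.

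The table has 22808 symbols, and the smallest total count of a gene in it is 2. Totals ran from 2567737 to 5569342 counts per library, which limits precision mainly for genes under a few CPM. Mitochondrial ribosomal RNA took 12.25% to 16.72% of counts. Within groups the correlation of log2 CPM (prior count 2) was at least 0.972, and between groups at most 0.859. Pairs of replicates were checked for duplication with a chi-square per gene over genes with at least 20 counts. It ran from 2.21 to 5.89, where sampling noise gives about 1, so all libraries were counted separately.

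Genes were kept by edgeR's filterByExpr with its defaults (minimum count 10, minimum total 15), which left 12366 genes with 99.46% of all counts. Counts were scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation and glmQLFTest, group as the only term, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 0.0745. Standard errors of log2 fold changes were taken as the size of the fold change over the square root of the F statistic. CPM values use the effective library sizes after TMM and are given with their SD over 4 libraries. Where every vehicle count was 0, the fold is a bound against a floor of 3 counts over the group. With 1 to 3 counts in a group, the ratio is given with an exact 95% interval that covers counting error only.

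Before the data were examined, 30 gene lists, the comparison, the alternatives and the rule for named genes were fixed. The rule names the 10 largest rises and falls among called genes with a mean of at least 5 CPM and no overlap between groups, up to 4 members with the smallest adjusted p per list with a mean of at least 1 CPM, 12 genes of prior interest whatever their values, and the 3 genes with the most counts. The 12 were MYOD1, MYOG, MYF5, MEF2C, MYH3, CDKN1A, CCND1, CDK4, CDK6, MET, HDAC1 and E2F3. Some genes that the rule names are not reported here. Lists with at least 5 tested members were compared with the other tested genes by camera (limma 3.58.1, inter-gene correlation 0.01), adjusted over the lists, with an estimated correlation and with fry as alternatives. Of the 14 lists past camera, 5 also passed with an estimated correlation: G1/S, G2/M, reported targets of miR-34 and miR-449a, lysosome and autophagy, and interferon. Lists of reported microRNA targets were written from general knowledge of the literature, not from these samples.

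For the site test, symbols were matched to GENCODE 29. By name 17606 matched, 521 matched through another symbol of the same gene and 4681 did not match, and 14006 had a 3′ UTR of at least 50 bases. The longest annotated 3′ UTR of each gene was used. The log2 fold change was regressed on the presence of a word with log2 3′ UTR length and GC content as further terms, for each of the 16384 words of 7 bases. The words were CACTGCC for miR-449a and CTTTATA for miR-340-5p, and CACTGCCA and CTTTATAA as 8-base forms. Site coordinates come from the annotated exons and are counted from 1. The labels name miR-340 without a strand, and the miR-340-5p strand was chosen before the data were examined.

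The tests were tried on simulated counts with means taken from the vehicle libraries, the real library sizes, 11827 genes and 200 changed genes. For treated against vehicle, edgeR recovered 48 of 67 genes changed 1.5-fold, 63 of 67 changed 2-fold and 66 of 66 changed 4-fold, with 10 calls among 11627 unchanged genes. Camera called 1 of 20 random lists, the shifted one. In the real data 67.3% of tested genes were called, so these figures do not show how the scaling and tests behave under so broad a change. Alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, a replicate block, leaving out each library, other thresholds, removal of mitochondrially encoded genes and, for sites, other covariates, 3′ UTRs and gene subsets. A correction for transcript GC content and length (spline with 5 degrees of freedom), scalings for the lists and other rankings of words were added after the data were seen. Site tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.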

Results

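RNA sequencing measured transcript abundance in RD18, a human cell line of fusion-negative rhabdomyosarcoma, a childhood tumour of skeletal muscle lineage that lacks the PAX fusion genes. Cells received the transfection reagent lipofectamine as vehicle, or the microRNAs miR-449a and miR-340, read here as the miR-340-5p strand. RNA was taken 60 h later, with 4 libraries in each group. The table holds read counts for 22808 gene symbols. Totals were 2567737, 4209215, 4650213 and 4033900 counts in the vehicle libraries and 5443379, 5569342, 2842165 and 2913944 in the treated libraries. No label says that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The vehicle libraries received no control RNA, so the comparison covers the microRNA pair together with the presence of transfected RNA.

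The comparison asks how the microRNA pair changed the transcriptome of these tumour cells. The treated cells had lower levels of the genes of DNA replication and mitosis and of most tested muscle genes, and higher levels of interferon-response and autophagy genes. Of 12366 tested genes, 4125 rose and 4199 fell (edgeR quasi-likelihood test, adjusted p under 0.05), and 4042 did not pass. At least 2-fold changes were found for 1542 of the genes that rose and 1622 of those that fell. In 7281 of the 12366 tested genes the groups did not overlap in any library, where chance gives 2.86% of genes. With library size as the only scaling, all genes shifted by a median of 0.138 log2 units and the calls split into 4890 higher and 3453 lower, so changes are stated relative to the typical tested gene.

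Among the 10 largest rises in genes averaging at least 5 CPM (counts scaled to a common library total) were those of STMN4, XAF1, NRP1, IFI27, WDR63, ID4, CFAP57, MX2 and FAM129A. STMN4, a stathmin family gene on chromosome 8 (27235323 to 27258420, GRCh38), had no count in any vehicle library and 16.4 ± 2.25 CPM (SD, n = 4) in treated cells, at least 80-fold higher against a floor of 3 counts over the group. XAF1, an interferon-induced gene on chromosome 17 (6755447 to 6775647), rose 251-fold, from 0.451 ± 0.345 to 110 ± 10.4 CPM (adjusted p = 1.15e-38). IFI27, also interferon-induced, rose 85.2-fold, and MX2, an antiviral GTPase gene, rose 36.2-fold. NRP1, a semaphorin and VEGF co-receptor, had 1 count in all vehicle libraries and 260 in treated libraries, a ratio of 218 with a counting interval from 38.8 to 8650. ID4, an inhibitor of basic helix-loop-helix factors, went from 3 to 163 counts, a ratio of 45.6 (15.3 to 223). WDR63 and CFAP57, both genes of motile cilia, went from 3 to 231 and from 5 to 234 counts. FAM129A rose 35.1-fold. These intervals cover counting error only.

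The 10 largest falls were those of HIST1H1A, KIF18B, TK1, CCNE2, FAM111B, SPC25, HIST1H2AJ, NRGN, AURKB and DLGAP5, most of them genes of the dividing cell. TK1, the thymidine kinase of S phase on chromosome 17 (78174075 to 78187233), fell from 39.6 ± 6.42 to 0.773 ± 0.440 CPM (51.2-fold lower, adjusted p = 3.28e-28). CCNE2, cyclin E2, was 39.7-fold lower. The mitotic kinase gene AURKB fell from 132 ± 3.57 to 4.13 ± 0.525 CPM, and the kinesin gene KIF18B was 56.6-fold lower. FAM111B was 38.5-fold, the kinetochore gene SPC25 37.3-fold, the spindle gene DLGAP5 31.3-fold and the neurogranin gene NRGN 31.9-fold lower. HIST1H1A fell from 173 to 2 counts, a ratio of 103 with a counting interval from 28.1 to 858, and HIST1H2AJ was 33.5-fold lower. Histone genes have near-identical copies, so these values are uncertain.

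**Figure D1:**
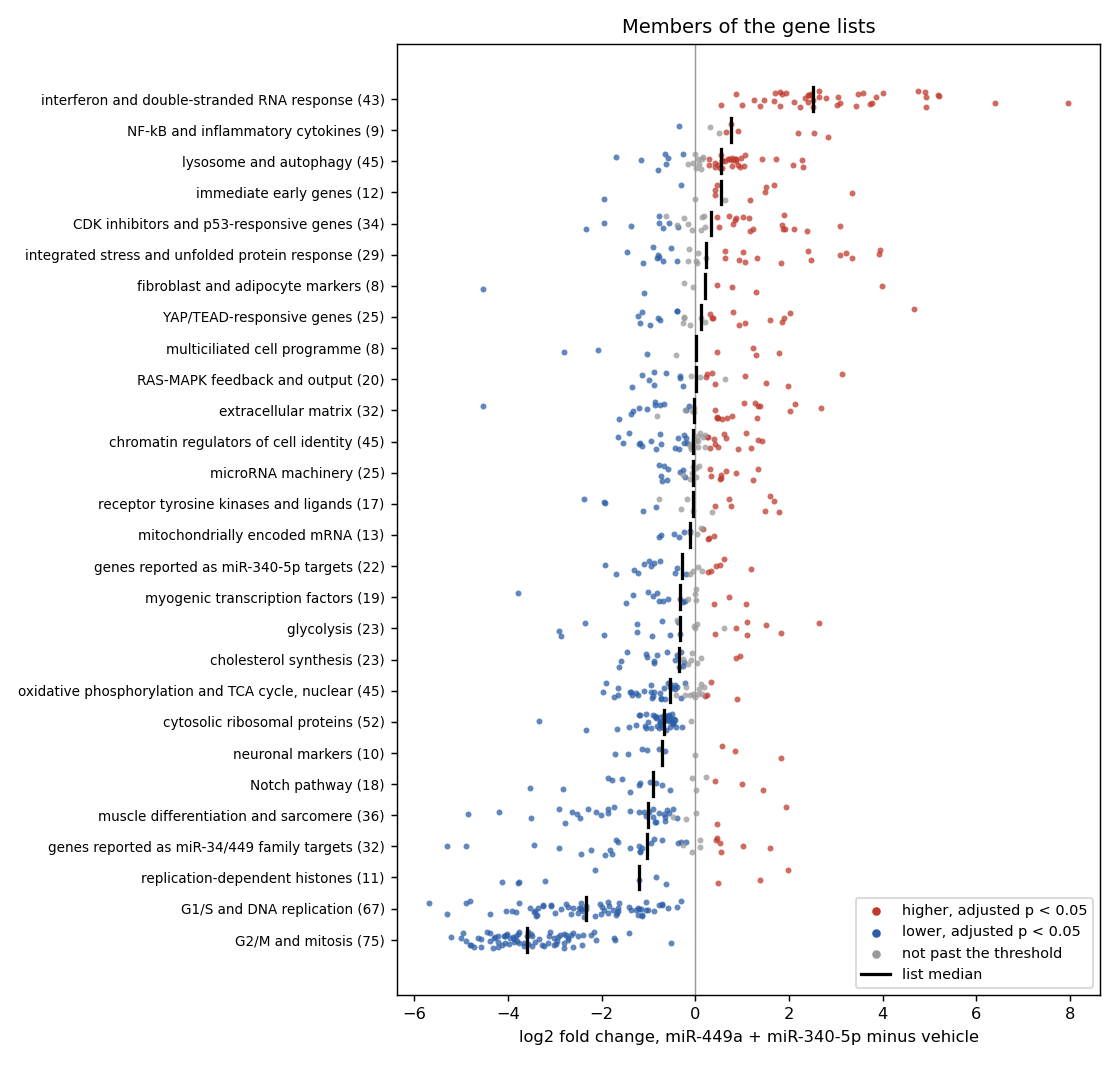
Log2 fold change of each tested member of the 28 gene lists with at least 5 tested genes, one dot per gene, with the list median as a black bar and the number of tested members in brackets. Red and blue dots are genes higher and lower in treated cells at an adjusted p under 0.05, and grey dots did not pass. The G2/M list has the lowest median (-3.58) and the interferon list the highest (2.52).

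Cell cycle genes fell together. All 67 tested members of the G1/S and DNA replication list and all 75 of the G2/M and mitosis list were lower in treated cells, with medians of -2.33 and -3.58 log2 units. RRM2 and TYMS, enzymes of deoxynucleotide supply, fell 27.9-fold and 29.8-fold, and HELLS, a chromatin remodeller, 5.02-fold. In mitosis, CENPE fell from 398 ± 26.5 to 26.5 ± 2.54 CPM (SD, n = 4), NUSAP1 was 14.1-fold lower, BIRC5 29.7-fold and UBE2C 21-fold. CDK4, the G1 kinase on chromosome 12 (57747727 to 57756013), fell from 288 ± 6.43 to 53.6 ± 2.04 CPM (log2 fold change -2.43, SE 0.07, adjusted p = 3.78e-37). CDK6 fell from 1260 ± 45.9 to 387 ± 21.4 CPM, 3.24-fold, and CCND1, cyclin D1, 1.85-fold. E2F3 fell 1.24-fold (log2 fold change -0.31, SE 0.08), a change that did not pass with library size as the only scaling (-0.17, adjusted p = 0.0513). Both lists passed the competitive test camera (adjusted p = 4.1e-45 and 1.9e-116) and also passed with an estimated correlation (adjusted p = 0.027 for each). With library size alone, 65 of the 67 G1/S genes were called lower.

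Of 34 tested CDK inhibitors and p53-responsive genes, 17 rose and 8 fell, with a median of 0.33. SESN2, a stress-induced regulator of mTORC1, rose 8.58-fold, the death receptor gene TNFRSF10B 3.79-fold, PMAIP1, which encodes the pro-apoptotic protein NOXA, 3.60-fold and the antiproliferative gene BTG1 2.23-fold. CDKN1A, which encodes the CDK inhibitor p21, measured 92.8 ± 4.48 CPM in vehicle and 102 ± 7.17 CPM in treated cells and did not pass (adjusted p = 0.152). It passed as higher with upper-quartile scaling (adjusted p = 0.0443) and with library size alone (0.00427). The list passed camera as higher (adjusted p = 0.0037), with adjusted p = 0.065 with an estimated correlation. Of 11 tested replication-dependent histone genes, 8 fell and 3 rose (median -1.20), led by HIST1H1B at 17.5-fold, HIST1H1C at 13.8-fold, HIST1H1E at 9.23-fold and HIST2H2AC at 4.39-fold lower. The list passed camera (adjusted p = 0.0014), with adjusted p = 0.25 with an estimated correlation. Across all 30 lists, counts adjusted over the list alone equalled those over all tested genes except for 5 against 4 rises in oxidative phosphorylation, 13 against 12 falls in extracellular matrix and 4 against 3 falls in the multiciliated list.

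Muscle genes were lower in treated cells. Of 36 tested genes of muscle differentiation and the sarcomere, 31 fell, 2 rose and 3 did not pass, with a median of -1.02. TNNI1, slow skeletal troponin I, fell from 98.9 ± 9.85 to 19.6 ± 5.02 CPM, 4.88-fold. The calcium pump gene ATP2A1 fell 7.49-fold, TNNT2 3.64-fold, the embryonic myosin gene MYH3 3.63-fold and the nebulin gene NEB 2.08-fold. The list passed camera (adjusted p = 3.3e-08) but not with an estimated correlation (adjusted p = 0.14 with an estimated correlation). Of 19 tested myogenic transcription factors, 12 fell and 3 rose (median -0.32), and that list did not pass camera (adjusted p = 0.061), although it did with a filter of 1 CPM in 4 libraries (0.039). MYOD1, the master regulator of the lineage on chromosome 11 (17719568 to 17722131), fell from 204 ± 21.7 to 108 ± 3.72 CPM (log2 fold change -0.91, SE 0.07, adjusted p = 4.33e-17). MYOG, myogenin, which acts later in differentiation, fell from 10.4 ± 1.89 to 0.646 ± 0.372 CPM (log2 fold change -3.78, SE 0.37), and MEF2C fell 2.51-fold. MYF5 was not analysed here.

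Neuronal markers and fibroblast and adipocyte markers moved both ways, and the 3 tested epithelial markers rose. Of 10 tested neuronal markers, 6 fell and 3 rose (camera adjusted p = 0.20). MAP2 fell 3.27-fold and STMN1 1.71-fold, while NCAM1 rose 1.49-fold and ENO2 3.54-fold. Of 8 fibroblast and adipocyte markers, 4 rose and 2 fell (adjusted p = 0.62), among them the contractile gene CNN1 at 15.9-fold and COL1A1 at 1.72-fold higher, and LUM at 23.3-fold and S100A4 at 2.14-fold lower. The epithelial list had 3 tested members, too few for the list test. All 3 rose: KRT18 1.69-fold, CLDN4 3.56-fold and KRT8 1.78-fold, the last lost with DESeq2 (adjusted p = 0.0503) and without vehicle replicate 1 (0.0595) or 4 (0.0706). No leukocyte or endothelial marker reached the count minimum. PTPRC, which encodes the pan-leukocyte protein CD45, averaged 1.49 CPM in vehicle and 1.44 CPM in treated libraries. Of 8 multiciliated cell genes, 4 rose and 3 fell (adjusted p = 0.68). The centriole duplication genes PLK4, CEP152 and SASS6 fell 6.95-fold, 4.23-fold and 2.05-fold, and the ciliary transcription factor gene RFX2 rose 2.35-fold.

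Interferon-response genes rose without exception. All 43 tested members of the interferon and double-stranded RNA response list were higher in treated cells, with a median of 2.52 log2 units. IFI6, on chromosome 1 (27666061 to 27672218), rose from 62.9 ± 6.53 to 1710 ± 126 CPM (27.1-fold, adjusted p = 8.51e-52). IFIT3, an antiviral effector gene, rose 5.73-fold. The list passed camera (adjusted p = 8.2e-53) and did so with an estimated correlation (adjusted p = 0.033). Of 9 tested genes of NF-kB and inflammatory cytokines, 6 rose and 1 fell (median 0.76), with camera adjusted p = 0.061. That list passed with the filter of 1 CPM (0.039) and without vehicle replicate 1 (0.045), 2 (0.047) or 4 (0.047) or treated replicate 3 (0.033). RELB rose 4.61-fold, CXCL1 7.11-fold, NFKB2 1.87-fold and SOD2 1.69-fold.

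Lysosome and autophagy genes were higher as a group. Of 45 tested lysosome and autophagy genes, 29 rose and 7 fell (median 0.56). The autophagy receptor gene SQSTM1 rose from 131 ± 6.60 to 640 ± 47.0 CPM, MAP1LC3B rose 4.28-fold, GABARAPL1 3.29-fold and WIPI1 4.90-fold. That list passed camera (adjusted p = 8.5e-05), also with an estimated correlation (adjusted p = 0.027). Of 29 tested genes of the integrated stress and unfolded protein responses, 14 rose and 9 fell (median 0.24). DDIT3, which encodes the transcription factor CHOP, rose 15.5-fold, ATF3 10.1-fold and PPP1R15A 5.31-fold. The stress list passed camera (adjusted p = 0.00064), with adjusted p = 0.067 with an estimated correlation. Of 12 tested immediate early genes, 8 rose and 2 fell (median 0.55), including JUN at 2.85-fold, JUNB at 3.23-fold and IER5 at 1.38-fold. This list passed camera (adjusted p = 0.0055), with adjusted p = 0.067 with an estimated correlation.

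Ribosomal protein genes were lower in treated cells, while lists of energy metabolism held genes that moved both ways. Of 52 tested cytosolic ribosomal protein genes, 51 fell and 1 did not pass (median -0.68). RPS3 fell 5.02-fold, RPS18 3.19-fold, RPLP0 2.68-fold and RPL32 2.26-fold, values that are uncertain because these genes have many processed pseudogenes. The list passed camera (adjusted p = 4.9e-21), with adjusted p = 0.097 with an estimated correlation. Of 45 nuclear genes of oxidative phosphorylation and the TCA cycle, 30 fell and 4 rose (median -0.55), among them MDH2 at 3.33-fold, CYCS at 3.13-fold, ATP5F1 at 3.94-fold and ATP5G3 at 2.32-fold lower. Camera gave adjusted p = 8.6e-06 for that list, with adjusted p = 0.097 with an estimated correlation. Of 23 glycolysis genes, 11 fell and 7 rose (median -0.32). LDHA fell 7.51-fold, TPI1 5.14-fold and ENO1 2.36-fold, while the glucose transporter gene SLC2A3 rose 6.24-fold. Camera gave adjusted p = 0.015 for glycolysis, with adjusted p = 0.26 with an estimated correlation. Of 23 cholesterol synthesis genes, 15 fell and 2 rose (median -0.35). SREBF2, the regulator of the pathway, fell 3.02-fold, and HMGCS1, an early enzyme of the pathway, 1.85-fold. Camera gave adjusted p = 0.041, with adjusted p = 0.31 with an estimated correlation. The cholesterol call was also lost with library size alone (0.064), after the GC content and length correction (0.051) and without treated replicate 1 (0.052). Of 13 mitochondrially encoded mRNAs, 6 fell and 4 rose (adjusted p = 0.65). MT-ATP6 fell 1.72-fold, MT-CO3 1.66-fold and MT-CO2 1.27-fold, and MT-ND5 rose 1.32-fold. The call of MT-CO2 was lost after the GC content and length correction (adjusted p = 0.0743). The 3 genes with the most counts were mitochondrial: MT-RNR2 (adjusted p = 0.493) and MT-RNR1 (0.0886) did not pass, and MT-ND2 rose 1.23-fold. MT-RNR1 passed as lower with limma-voom (adjusted p = 2.22e-05), with the replicate block (1.01e-05) and without vehicle replicate 4 (0.0046). MT-RNR2 passed as lower without vehicle replicate 4 (0.0417).

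Signalling and chromatin lists held genes that moved both ways. Of 18 Notch pathway genes, 12 fell and 3 rose (median -0.91, camera adjusted p = 0.061). The Notch list passed with the filter of 1 CPM (0.038), after the GC content and length correction (0.041) and without vehicle replicate 1 (0.046) or 4 (0.047). The Notch effectors HES1 and HEYL fell 11.5-fold and 7.12-fold, the ligand JAG2 2.31-fold, and RBPJ, the DNA-binding partner of Notch, rose 2.01-fold. Of 17 receptor tyrosine kinases and ligands, 7 rose and 5 fell (adjusted p = 0.86). MET, the hepatocyte growth factor receptor on chromosome 7 (116672390 to 116798386), fell from 42.3 ± 4.18 to 11.3 ± 1.36 CPM, FGFR4 5.16-fold and ERBB3 3.86-fold, and the collagen receptor DDR2 rose 3.46-fold. Of 20 genes of RAS-MAPK feedback and output, 8 rose and 9 fell (adjusted p = 0.88), with IER3 8.74-fold higher and SPRY1 2.55-fold and HMGA2 1.85-fold lower. Of 25 YAP/TEAD-responsive genes, 11 rose and 8 fell (adjusted p = 0.20). NT5E rose 25.7-fold, MYOF 4.06-fold and FJX1 3.59-fold, and ASAP1 fell 2.26-fold. Of 32 extracellular matrix genes, 15 rose and 12 fell (adjusted p = 0.65). COL5A1 rose 4.07-fold and COL6A1 2.62-fold, and COL4A2 fell 3.11-fold and SPARC 2.6-fold. Of 45 chromatin regulators, 13 rose and 17 fell (adjusted p = 0.68). The histone methyltransferase gene EZH2 fell 3.12-fold, DNMT1 2.29-fold and HDAC1 2.26-fold, and KDM5A rose 1.88-fold. Of 25 genes of the microRNA machinery, 9 rose and 9 fell (adjusted p = 0.45), including TNRC6B at 2.34-fold, AGO2 at 1.84-fold, TNRC6A at 1.57-fold and DDX6 at 1.47-fold higher. The median, mean and test differed in sign for the RAS-MAPK, receptor tyrosine kinase, extracellular matrix, microRNA machinery and multiciliated lists. With library size alone the medians of the receptor tyrosine kinase, extracellular matrix, microRNA machinery, chromatin and mitochondrial mRNA lists turned positive, and those of the extracellular matrix, microRNA machinery and chromatin lists did so with upper-quartile scaling too.

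**Figure D2:**
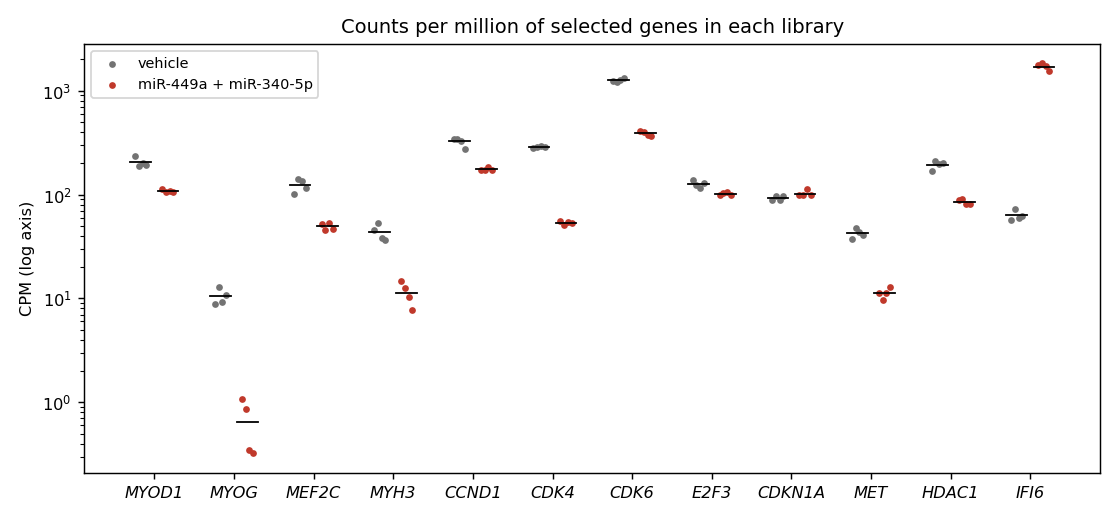
CPM on a log axis for genes fixed in advance and for the interferon-response gene IFI6, one dot per library, with the group mean as a black line. The treated libraries lie below all vehicle libraries for MYOD1, MYOG, CDK4 and CDK6 and above them for IFI6, and the mean of CDKN1A is 92.8 CPM in vehicle and 102 CPM in treated cells.

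Genes reported as targets of the transfected microRNAs were compared next. Of 32 tested genes reported for the family of miR-34 and miR-449a, 22 fell and 6 rose (median -1.04). LDHA fell from 447 ± 14.1 to 59.3 ± 4.57 CPM, and HDAC1 from 193 ± 18.2 to 85.4 ± 4.56 CPM. The list passed camera (adjusted p = 3e-07), also with an estimated correlation (adjusted p = 0.041). It shares 7 tested genes with the cell cycle lists. Among its other 25, 15 fell and 6 rose (median -0.72). The 22 members whose 3′ UTR holds the miR-449a word had a median of -1.06. The 5 members with the word of neither microRNA had a median of -1.13, so the fall of this list cannot be credited to the miR-449a word alone. Of 22 tested genes reported for miR-340-5p, 12 fell and 6 rose (median -0.29), and that list did not pass (adjusted p = 0.061). It passed with the filter of 1 CPM (0.039) and after the GC content and length correction (0.029). In that list, the 6 members whose 3′ UTR holds the miR-449a word had a median of -1.15. The 3 members with the word of neither microRNA had a median of 0.54, so the fall cannot be credited to miR-340-5p alone. RHOA fell 2.34-fold and SKP2 2.13-fold, and JAK1 rose 2.28-fold.

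The annotated 3′ UTRs of GENCODE v29 on GRCh38 were searched for the 7-base words that pair with bases 2 to 8 of each microRNA. For miR-449a the word is CACTGCC. It occurs in 2 places in the 3′ UTR of CDK6 on chromosome 7, minus strand, at 92614046 to 92614052 (TTCTGCCACACACTGCCTTGTTGGCAA) and at 92605953 to 92605959. MET also has 2, at 116796175 to 116796181 and 116798289 to 116798295 on the plus strand of chromosome 7. LDHA has 1 in the 3′ UTR on chromosome 11 at 18407538 to 18407544, HDAC1 1 on chromosome 1 at 32333503 to 32333509, CCNE2 1 on chromosome 8 at 94881503 to 94881509, and E2F3 1 on chromosome 6 at 20493160 to 20493166. For miR-340-5p the word is CTTTATA. CDK6 has 2 of these, at 92613507 to 92613513 and 92609356 to 92609362, and CCND1 has 1 on chromosome 11 at 69651867 to 69651873. Of 20 named genes with the miR-449a word, 15 fell and 5 rose, the latter being FAM129A, SOD2, IER5, AGO2 with 2 words and TNRC6B with 3. Of 15 named genes with the miR-340-5p word, 9 fell and 6 rose, the latter being JAK1, DDR2, RBPJ, NT5E, SOD2 and KRT8. The 3′ UTRs of MYOD1, MYOG, MEF2C, BIRC5 and HES1 hold 0 of either word.

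Genes with miR-449a sites were lower as a group. Among 10793 tested protein-coding genes with a 3′ UTR, the 1911 with the miR-449a word had a median log2 fold change of -0.14, against 0.055 for the 8882 without it. Of those with the word 41.5% fell, against 32.1% of those without. The 645 genes with the 8-base form had a median of -0.28, the 327 with 2 or more of the 7-base words -0.28, and the 1584 with 1 of them -0.12. With 3′ UTR length and GC content in the model, the word carried a coefficient of -0.27 log2 units (SE 0.03). That ranked 17 from the lowest among all 16384 words by coefficient and 1 by coefficient over SE. The words next in order by that measure, ACTGCCA and TACTGCC, share 6 bases with it. After them came TGCTGCC, GCTGCCA, CTGCCAC, CTGCCAG and CCTGCCA, with coefficients from -0.236 to -0.199. These hold CTGCC but not the 6 bases ACTGCC, so the shift was not confined to words that hold those 6 bases.

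Genes with the miR-340-5p word did not shift by a comparable amount. The 2134 genes with that word had a median log2 fold change of 0.03, against 0.02 for the 8659 without it. The coefficient was -0.04 (SE 0.03), with a 95% interval from -0.095 to 0.02, and ranked 2577 by coefficient and 1383 by coefficient over SE. Genes with the miR-340-5p word alone had a median of 0.09, genes with the miR-449a word alone -0.17, genes with both -0.08 and genes with neither 0.05. Genes are not independent replicates, so the ranks among words stand in place of p-values. In simulated data, fold changes were shuffled over genes and a shift of -0.1 was added to genes with the miR-340-5p word. The shift was estimated at -0.11 and ranked 13 by coefficient over SE, although by coefficient it lay outside the lowest 1% of words. Shuffling removes the real effects of other words, so the same shift could rank less low in the real data.

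**Figure D3:**
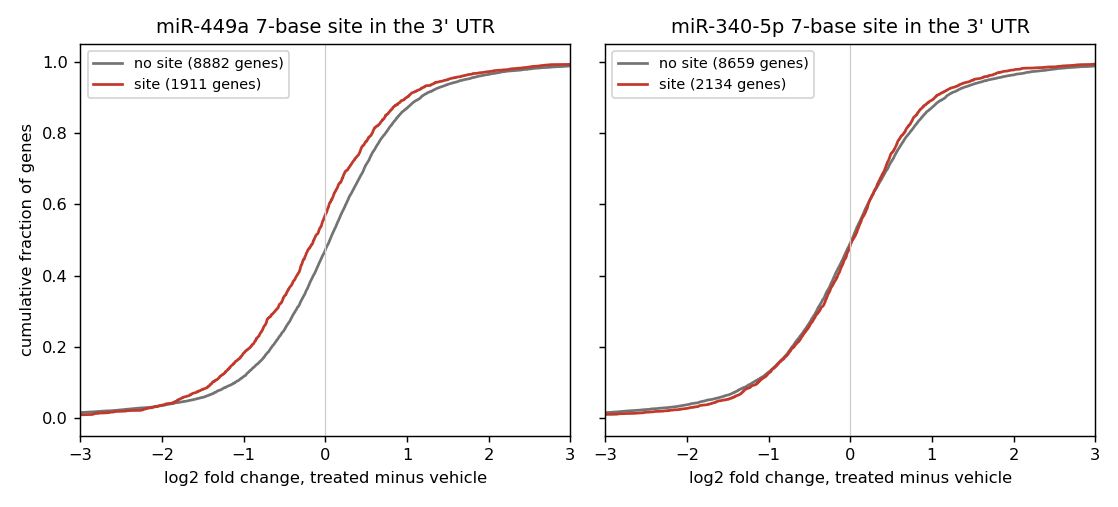
Cumulative fraction of genes by log2 fold change for tested protein-coding genes with and without the 7-base word of miR-449a (left) and of miR-340-5p (right) in the 3′ UTR. The curve of the 1911 genes with the miR-449a word lies to the left of the curve without it over most of its length, while the curves for miR-340-5p nearly coincide.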

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

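The tests of leukocyte RNA, unrelated transfected RNA, direct pairing in muscle genes, dilution, number of genes with the miR-340-5p word, the other miR-340 strand and the splits of all words were chosen only after the result was seen. Chance was tested by refitting all 35 splits of the 8 libraries into 4 and 4. For genes called by edgeR, 1 of the 35 splits, the real one, gave as many as the real 8324, and the highest of the others gave 0, with at most 709 genes at an unadjusted p under 0.05 and 0 by limma-voom. For gene lists past camera, 1 of 35 splits reached the real 14, with 12 as the highest of the others. The 16 splits that kept 3 libraries of a group together gave 8 to 12 lists, and the 18 that kept 2 together gave 0 or 1, a structure that follows the groups. For the miR-449a word, 1 of 35 splits had a coefficient as far from 0 as the real -0.27, with 0.14 as the farthest of the others. For the miR-340-5p word, 1 of 35 splits was as far from 0 as the real -0.04, with -0.025 as the farthest of the others. Of all 16384 words, 69.8% had their farthest coefficient in the real split, so the splits decide nothing about either word. Chance is argued against for the counts of genes and of lists, at a share of 1 in 35, the smallest that 35 splits can give. The splits cannot tell the treatment from any other difference between the groups of libraries.

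Interferon-response genes rose in all 43 tested members, and that rise held in direction and call under each scaling. RNA from leukocytes as the whole account is argued against: the 6 leukocyte markers in the table summed to 47 counts in treated and 52 in vehicle libraries, a ratio with an upper bound of 1.146, which allows 0.515 CPM more of them beside a summed interferon-gene rise of 5894 CPM and a median rise of 5.75-fold. That bound was revised after 2 stricter limits, no treated marker above 1 CPM and a ratio under 1, had not been met, the former by PTPRC at 1.44 CPM in treated and 1.49 CPM in vehicle libraries. Transfected RNA as such cannot be told apart from the microRNA sequences, because 0 libraries received an unrelated RNA. A response to double-stranded RNA in general and an effect of miR-449a or miR-340-5p targets therefore both stay open as hypotheses.

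Muscle genes fell in 31 of 36 tested members. The 30 members whose 3′ UTR holds neither the miR-449a word nor the miR-340-5p word had a median of -1.02. Pairing through those words as the whole account is therefore argued against. Related words, such as ACTGCCA, which came next in order after the miR-449a word, were not counted as sites. Direct pairing through such words was not tested in muscle genes and stays open. Dilution by cells of another type would lower muscle genes by about the same factor. The interquartile range of their log2 fold changes was 1.52, but that of all tested genes was already 1.13, so dilution stays open. An effect that passes through other genes, such as the lower MYOD1 and MYOG, may account for the fall and was not tested.

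Genes with miR-340-5p words did not fall like genes with miR-449a words. Too few genes with the word is argued against, since 2134 genes held it, against 1911 with the miR-449a word. The lower bound of its 95% interval, -0.095, also lay above the miR-449a coefficient of -0.27. That interval treats genes as independent replicates, so it may be too narrow. The word of the other miR-340 strand, GAGACGG, stood at the 10.9 percentile of all words by coefficient over SE, outside the lowest 5%. By the same measure the miR-340-5p word ranked 1383 of 16384. The test therefore hardly sets the strands apart, and an effect of the other strand stays open. Base composition stays open: among the 896 words with as many G and C bases, the miR-340-5p word stood at the 3.7 percentile, between the limits of 1 and 5 set in advance. A small effect of miR-340-5p that AT-rich words hide could therefore be present, and the amount of active miR-340-5p was not measured.

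Of 352 groups of 4 values tested for a library far from the other 3, 15 had one, where chance gives about 5%. The gap to the nearest library as a share of the range was 1 for HIST1H1A in treated replicate 1 and for NRP1 in vehicle replicate 4, each the only library of its group with a count. It was 0.946 for CDKN1A in treated replicate 3 (113 CPM against 98.1 to 98.9), 0.914 for ATP5F1 in vehicle replicate 3 (90.3 against 114 to 116) and 0.898 for HIST2H2AC in vehicle replicate 3 (27.2 against 18.8 to 19.7). KIF18B had 0.907 in vehicle replicate 4, PPIA 0.896 in treated replicate 3, IFIT3 0.860 in vehicle replicate 1 and JAG2 0.852 in vehicle replicate 4. TUBA1B had 0.840 in vehicle replicate 2, PGK1 0.838 in vehicle replicate 3 and MT-ND2 0.837 in treated replicate 1. The mean log2 CPM of the cholesterol synthesis list stood apart in treated replicate 2 (0.918), and that of the histone list in vehicle replicate 4 (0.836).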

How the results depend on the processing

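The GC content and length correction, the scalings of the lists and the other rankings of words were added after the data were seen. Under the scalings, filters, tests and left-out libraries, counts of called genes stayed within 1.5 times of 4125 higher and 4199 lower. DESeq2 gave 4139 and 3930, limma-voom 4139 and 4220, upper-quartile scaling 4381 and 3922, library size alone 4890 and 3453, no filter 4679 and 4386, and the GC content and length correction 4069 and 3921, where 1 called gene reversed. Leaving out each library gave 3942 to 4142 higher and 4004 to 4173 lower. A required fold change of 2 left 1542 and 1622, because it removes smaller changes by construction. No label says that replicate numbers pair the libraries. Same-number correlations of deviations were small, 0.013 to 0.056, but 7 of 8 libraries matched their own number best. That is a hint of pairing from the data, not the design. The replicate block gave 4102 higher, 4171 lower and 14 lists. Lists past the test numbered 14 with the preset correlation, 5 with an estimated one and 25 with fry, which does not compare a list with other genes, and 13 to 16 without each library. The miR-449a coefficient of -0.27 ranged from -0.20 without covariates to -0.40 for 8-base sites alone, and the miR-340-5p coefficient of -0.04 from -0.05 without the cell cycle lists to -0.01 without covariates; neither changed sides of the lowest 1% of words. Of 146 named genes, 139 kept direction and call under every scaling, filter, test, correction, replicate block and left-out library, and 0 reversed. The stricter thresholds of p and fold change were not part of that count. The cause of the calls that changed was not tested. Totals of 2567737 to 5569342 counts limit genes under a few CPM.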

Other observations

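The genes of this part were chosen after their values were seen, and the tests of other microRNA families and of the motile cilium were set before their results. Several genes used as references for normalization were far lower in treated cells. GAPDH, a glycolytic enzyme gene, fell from 4259 ± 211 to 588 ± 97.9 CPM (SD, n = 4, 7.24-fold), and TUBA1B, an alpha-tubulin gene, from 2072 ± 78.4 to 277 ± 31.1 CPM. ACTB fell 2.62-fold, PPIA 2.03-fold, PGK1 1.90-fold, HPRT1 1.71-fold, YWHAZ 1.64-fold and TBP 1.57-fold. B2M, an interferon-responsive gene, rose 1.47-fold and the nuclear RNA MALAT1 2.09-fold. GAPDH, TUBA1B, ACTB and PPIA have processed pseudogenes, so reads may be split between copies; the fall of GAPDH stands beside 8 other reference genes, of which B2M alone rose, and beside 4890 higher and 3453 lower genes with library size as the only scaling.

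IGF2, a growth factor gene with high expression in these cells, averaged 9171 ± 2289 CPM in vehicle and 11760 ± 530 CPM in treated libraries and did not pass (adjusted p = 0.103). It passed as higher with limma-voom (4.31e-06), with the replicate block (0.014), with library size alone (0.0234) and without vehicle replicate 2 (9.46e-11).

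Genes of the motile cilium, the beating form of the organelle, stood out among the largest rises: CCDC113 rose 31.0-fold beside WDR63 and CFAP57. A list of other motile cilium genes was then tested, leaving those 3 out. Of 74 listed members, 1 was found in the table under another symbol, in a lookup added after the values were seen, and 47 were not tested because they were not found in the table or had too few counts; a low gene that rose reaches the count minimum more easily than a low gene that fell. Of the 27 tested members, 21 rose and 3 fell, with a median log2 fold change of 1.30. That median stood at the 100 percentile of 10000 random lists matched on expression. The 34 members that were in the table but not tested summed to 111 counts in vehicle and 624 in treated libraries, a scaled ratio of 4.71 with a counting interval from 3.84 to 5.82, a sum chosen after the values were seen. DNAAF1, a dynein assembly factor, had a log2 fold change of 5.20, WDR78 3.53, CCDC65 3.32 and RSPH4A 2.82, and MNS1 -2.36. A candidate explanation is that many motile cilium genes rose in these cells, a hypothesis that needs cilia to be looked at directly. The multiciliated cell list fixed in advance, which holds centriole genes as well, did not pass.

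Words that rose with treatment included AGCACTT and GCACTTT, the sites of the miR-302 and miR-17 families, with coefficients of 0.157 and 0.137. The rest of the 10 words with the highest coefficient over SE were AATGGAA, CAGGAGA, GAAACCC, AAAAAAA, CAAAAAA, CCAACAT, ACAAAAA and ATTTATT. None of these is a word of the families tested here, so the rise was not particular to microRNA families. Of 21 other microRNA families, 17 had a positive coefficient over SE, with a mean of 0.74. That mean stood at the 96.6 percentile of 10000 random sets of words of the same G and C content. The word of miR-25/92, GTGCAAT, had a coefficient of 0.135 (SE 0.033), while those of miR-15/16 and miR-138 were -0.053 and -0.109. This may reflect release of targets of microRNAs the cells already had, through competition for Argonaute. Some family words overlap, so they are not independent, and no small RNA was measured.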
